A study of Arabidopsis thaliana with 12 samples.

How the data were processed

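RNA of whole seedlings grown on plant nutrient medium under continuous light was sequenced, per the labels, as poly-A selected libraries with paired-end reads on an Illumina NovaSeq instrument. The age is given as 6 days in the series design and as 8 days in the growth protocol, and the difference could not be settled. There were 4 genotypes, Col-0, atg2-4, lon2-8 and lon2-8 atg2-4, with 3 libraries each, which the series design calls biological replicates. No growth, harvest or sequencing batch is given. For the 6 single-mutant samples the title and the genotype tag name opposite mutants. The 12 columns of the deposited table are named by genotype and number, and each was assigned to the group in its name, with 0 columns left unassigned. Library numbers follow the column names and were not matched to single sample records.

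Per the submitters' processing notes, the tools used were bcl2fastq, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5, Salmon 0.8.2, edgeR and limma; the role of each, the genome build and the use of strand are not given in the sources used here. The authors deposited FPKM per gene and library, and the mean FPKM of each group. For 4 comparisons the deposited tables also hold, per the file headers, a score for each gene, a p-value and a false discovery rate from a test that is not stated, and a log2 fold change that equals the log2 of the ratio of mean FPKM by the authors. The authors' direction was read from these tables and set beside the results as counts and shared genes, with the authors' log2 fold changes given for LON2 alone. Names and the order of neighbouring genes came from the RefSeq annotation of assembly TAIR10.1, to which 26093 of 26093 identifiers matched, and no coordinates are given.

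FPKM values of each gene were whole multiples of 1 step per library, within a tolerance of 0.01 fragments, for 26093 of 26093 genes. The relative depth was read from the 3520 genes with a mean under 0.3 FPKM, and the fragments of each library were recovered and added up, which gave 14481170 to 18690658 fragments. The chi-square of replicates per gene against counting noise alone was 1.61 to 2.84, where 1 is the value of counting noise, so no replicates differed by less than sampling allows. Precision is limited by the 3 libraries per group and, for genes at a few FPKM, by the number of fragments.

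Genes with at least 1 FPKM in at least 3 libraries were tested, 20662 of 26093. Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 for all 12 libraries in 1 model with a mean for each group, moderated with a trend, and p was adjusted by Benjamini-Hochberg over the genes tested in each comparison, with a threshold of 0.05. The test is two-sided. The comparisons were atg2-4, lon2-8 and the double mutant against Col-0, the double mutant against each single mutant, and the interaction, which is the effect of lon2-8 in the atg2-4 background minus that in Col-0. A size limit of 2-fold was counted beside the threshold. Comparisons against Col-0 share its libraries, so overlaps of calls are mostly given between comparisons that share none. The iron deficiency list is an exception, where draws of unchanged groups that share the Col-0 libraries stand beside the count. The interaction calls of the 20 genes named by size in lon2-8 are another exception, and no draws stand beside these. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

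The tests, the alternatives, the groups, the rule for naming genes and 22 gene lists were fixed before the data were examined. The lists cover peroxins, β-oxidation and the glyoxylate cycle, photorespiration and catalase, LON and DEG proteases, autophagy, proteasome subunits, heat shock proteins, the ER unfolded protein response, oxidative stress, salicylic acid and immune response, jasmonate, senescence, carbon starvation and branched-chain amino acid breakdown, photosynthesis, seed storage, root markers, mitosis, auxin response, anthocyanins, aliphatic glucosinolates, iron deficiency and phosphate starvation. They hold 431 entries for 430 genes, of which 426 are in the deposited table. HSP21, APX2, THI2.1 and SAG12 were not analysed here, and other members under the FPKM filter were not tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, which compares the members with all other genes, and p was adjusted over all 22 lists and 6 comparisons; the same test with an estimated correlation was run beside it.

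Genes were named by this rule. LON2 and ATG2 were named in every comparison. For each comparison against Col-0 and for the double mutant against atg2-4, the 10 largest rises and 10 largest falls were taken among genes that passed and whose 3 libraries of one group all lay beyond the 3 of the other. For each list and comparison, up to 4 members of smallest adjusted p were taken, or, where no member passed, at most 2 members as values only. For the interaction and for the double mutant against lon2-8, the 5 genes of smallest adjusted p in each direction were taken. The text names a part of these. Genes named in a comparison where this rule does not select them (MAD1 and IMPA-1 in further groups, MLS in the double mutant, WRKY33 in the double mutant against atg2-4, FER1 and FIT in atg2-4, and the effects in each background of genes with an interaction) and those of the added lists were chosen after their values were seen.

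The alternatives in each model were a pseudocount of 0.1, no filter, a filter of 5 FPKM in 3 libraries, quantile normalization, centring each library on the median log2 ratio, limma's array weights, the library number as a block, only the libraries of the groups compared, and each library left out in turn. Voom on the recovered fragments, the same scalings for the lists and 5 further lists (hypoxia, sulfur starvation, type-A cytokinin response regulators, camalexin and cyanogenic defence, late embryo and dehydration proteins) were added after seeing the data. The median log2 fold change of all genes stayed within 0.1 of 0 under each scaling, at −0.0471 in atg2-4 and −0.0419 in lon2-8 as deposited. The code was tested on simulated data drawn from the Col-0 means, with the same spread beyond counting noise for every gene. In each comparison of groups, 100 genes were changed by 1 and 100 by 0.5 log2. At 1 log2, 86 to 89% were recovered and at 0.5 log2, 71 to 81%. Of the calls, 5.11 to 6.70% were false, and 0 of 22 lists were called in any comparison with no list changed. Far fewer genes were changed in these draws than in the data, so the shares recovered and false may not carry over to the data. Each gene was drawn independently of the others, so false list calls from correlation between genes were not checked.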

Results

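Messenger RNA was sequenced from whole Arabidopsis seedlings of 4 genotypes, the wild type Col-0, the autophagy mutant atg2-4, the peroxisomal protease mutant lon2-8 and the lon2-8 atg2-4 double mutant, with 3 libraries of each. The deposited table gives FPKM (fragments per kilobase of transcript, scaled to library size) for 26093 genes in the 12 libraries. Every value could be read back as a whole number of fragments within 0.01, which gave 16786861, 18458822 and 15868471 fragments in the Col-0 libraries, 16763343, 14481170 and 18175326 in atg2-4, 15560955, 18412522 and 17948410 in lon2-8, and 18690658, 17881587 and 16478647 in the double mutant. Between 19705 and 19923 genes had at least 1 FPKM in a library, and the 10 most abundant genes took 5.72 to 6.35% of the fragments. The replicates of each group correlated at r = 0.994 to 0.995 across genes, which are not independent replicates. Changes are given as log2 fold changes with their standard error, on the log2(FPKM + 1) scale, which understates the changes of genes at low FPKM. FPKM values are means with their SD over 3 libraries, and adjusted p values come from limma over the 20662 genes tested. Genes are said to rise or fall where the adjusted p was under 0.05.

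LON2 (AT5G47040), which encodes the Lon protease of the peroxisome matrix, was listed at 24.7, 25.3 and 27.8 FPKM in the Col-0 libraries and at 23.2, 21.9 and 21.7 in the atg2-4 libraries. It was at 12.0, 11.1 and 11.7 in lon2-8 and at 4.45, 4.53 and 5.36 in the double mutant. The mean fell from 25.9 ± 1.6 FPKM in Col-0 to 11.6 ± 0.47 in lon2-8 (−1.09 ± 0.064 log2, adjusted p = 1.06e-07) and to 4.78 ± 0.50 in the double mutant (−2.22 ± 0.064, adjusted p = 1.42e-11). Relative to lon2-8, the double mutant had 0.412 times the LON2 level (adjusted p = 1.12e-08). LON2 also passed as lower in atg2-4 (−0.21 ± 0.064, adjusted p = 0.0163), a call that was lost without Col-0 library 3 (adjusted p = 0.0763) or without atg2-4 library 3 (adjusted p = 0.0546). ATG2 (AT3G19190), which encodes a lipid transfer protein needed for autophagosome growth, was at 7.85, 7.6 and 7.67 FPKM in Col-0, 6.66, 5.98 and 6.31 in atg2-4, 7.96, 7.79 and 7.0 in lon2-8 and 6.41, 6.28 and 7.07 in the double mutant. The fall of ATG2 was small in atg2-4 (−0.25 ± 0.061, adjusted p = 0.00398) and in the double mutant (−0.20 ± 0.061, adjusted p = 0.0141). The latter call was lost without double mutant library 2 (adjusted p = 0.0572). The adjusted p of ATG2 in lon2-8 was 0.823. The samples of both single mutants carry titles and genotype tags that name opposite mutants, so the groups used here rest on the column names of the deposited table, and LON2 was low in the columns named for lon2-8. IMPA-1, which encodes an importin and lies on the same chromosome as ATG2, was low in both groups with atg2-4. It was at 27.4 ± 0.96 FPKM in Col-0, 26.3 ± 0.26 in lon2-8, 3.31 ± 0.065 in atg2-4 and 4.01 ± 0.30 in the double mutant. Whether a second sequence change is carried with atg2-4 was not tested. MAD1, a spindle checkpoint gene on the same chromosome as LON2, followed LON2, with 5.10 ± 0.13 FPKM in Col-0, 5.38 ± 0.25 in atg2-4, 2.01 ± 0.12 in lon2-8 and 1.12 ± 0.038 in the double mutant. LON2 and MAD1 were among 4 tested genes that fell by over 0.9 log2 with lon2-8 in both backgrounds. The values of IMPA-1 and MAD1 in the groups for which the rule on named genes did not select them were looked up after the comparisons had been seen.

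**Figure D1:**
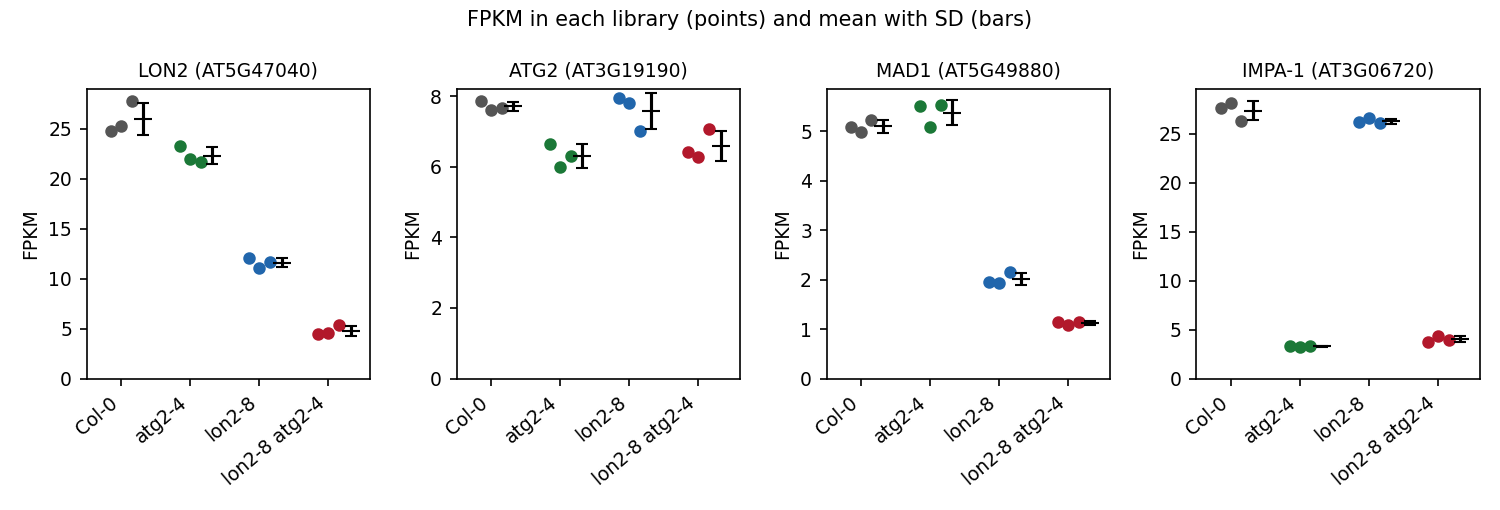
FPKM of LON2, ATG2, MAD1 and IMPA-1 in each of the 12 libraries (points) of the 4 genotypes, with the mean and SD of 3 libraries (bars). LON2 and MAD1 are lower in lon2-8 and lower still in the double mutant, IMPA-1 is low in both groups that carry atg2-4, and ATG2 differs little between the 4 groups.

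The libraries fell into the 4 genotypes along the first and second principal components. The first component held 70.8% of the variance and separated the groups with atg2-4 from those without it. Scores on it ran from 32.5 to 34.8 in atg2-4 and the double mutant. The second component held 9.56% and separated Col-0, at 16.4 to 17.65, from lon2-8, at −18.8 to −16.5, while atg2-4 and the double mutant lay closer together, at 3.04 to 4.46 and −3.85 to −2.53. The third component held 4.52% and separated atg2-4, at −13.1 to −9.82, from the double mutant, at 9.67 to 13.3, while Col-0 and lon2-8 lay closer together on it, at 1.60 to 2.72 and −4.58 to −0.385.

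**Figure D2:**
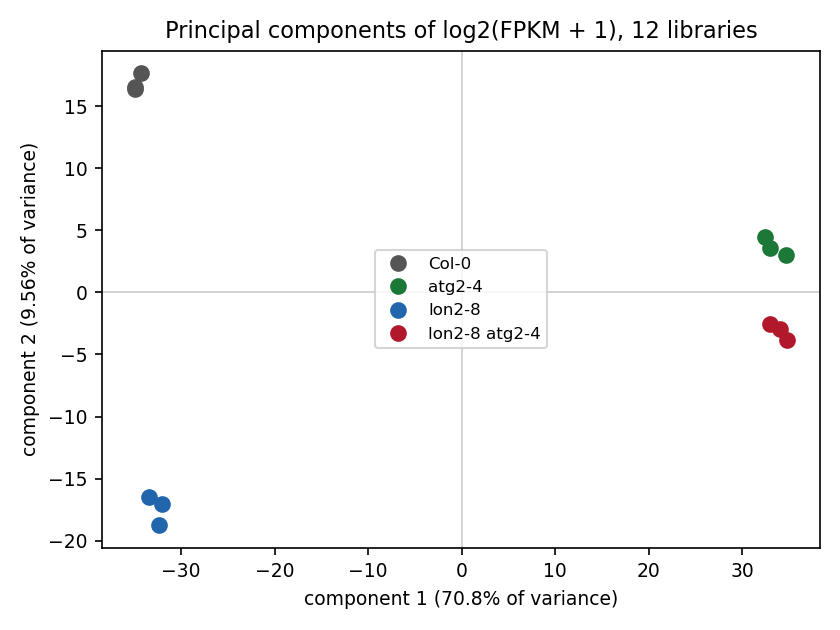
Scores of the 12 libraries on principal components 1 (70.8% of the variance) and 2 (9.56%) of log2(FPKM + 1), coloured by genotype. The distance between Col-0 and lon2-8 along component 2 is larger than that between atg2-4 and the double mutant.

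The comparison of atg2-4 with Col-0 asks what atg2-4 does to the transcriptome of seedlings. Genes of the salicylic acid and immune response rose most as a group, with 21 of 22 members higher (n = 3 libraries per genotype). PBS3, which encodes an enzyme of salicylic acid synthesis, rose from 0.388 ± 0.17 to 30.0 ± 1.8 FPKM (4.49 ± 0.097 log2, adjusted p = 8.04e-13). The transcription factor gene CBP60G rose from 4.30 ± 0.20 to 64.8 ± 0.88 FPKM (3.64 ± 0.051, adjusted p = 1.05e-14). Autophagy genes rose too, among them the cargo receptor gene NBR1, from 55.7 to 123 FPKM (1.13 ± 0.030, adjusted p = 5.73e-12). Genes of aliphatic glucosinolate and anthocyanin synthesis fell. In all, 10027 of the 20662 genes tested changed (48.5%), 4403 upward and 5624 downward, and 810 of them by at least 2-fold, of which 677 rose and 133 fell. The share of changed genes that were higher was 43.9%, and 52.1% when each library was centred on its median, so which direction held more genes depends on the scaling.

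The 10 largest rises were in genes at under 1 FPKM in Col-0, apart from GLP9. AT1G26240, which encodes a proline-rich extensin-like protein, rose from 0.527 to 645 ± 19 FPKM (8.72 ± 0.11, adjusted p = 5.99e-15). AT1G26390, of the berberine bridge enzyme family, reached 353 ± 16 FPKM (7.85 ± 0.059, adjusted p = 5.88e-17), and the germin-like gene GLP9 rose from 2.94 ± 0.65 to 725 ± 50.4 FPKM. The cupin gene AT5G38910 and AT3G55790 were listed at 0 in all Col-0 libraries and at 131 ± 11 and 93.3 ± 13 FPKM in atg2-4. CYP82C2, a cytochrome P450 of indolic cyanogenic defence, rose from 0.0736 to 77.9 ± 4.7 FPKM (6.2 ± 0.092, adjusted p = 2.03e-14). The others were AT1G58320 of the PLAC8 family, AT1G29100 with a heavy-metal domain, the lectin receptor kinase gene AT2G29220 and AT1G08763, a locus without a known product whose reads may be shared with a neighbour, since the use of strand is not given in the sources used here. Among the 10 largest falls, the defensin-like gene AT2G36255 went from 16.7 ± 1.5 FPKM in Col-0 to 0 in all atg2-4 libraries, AT5G33355 from 26.1 ± 0.96 to 0.756 ± 0.090, and AT3G59930 from 43.8 ± 0.50 to 3.70 ± 0.42. The detoxification gene CYP81D11 fell to 0.956 ± 0.11 FPKM (−2.84 ± 0.099, adjusted p = 9.22e-11), IMPA-1 fell to 0.121 times its Col-0 level (−2.72 ± 0.049, adjusted p = 1.72e-13), and the arabinogalactan protein gene AGP30 went from 33.5 ± 4.6 to 4.97 ± 0.35 FPKM. The defensin-like LCR85, AT2G16005 and the overlapping pair AT1G34047 and AT1G34049 made up the rest.

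Of the 22 fixed lists, 11 passed in this comparison. The salicylic acid and immune response list (median 1.89, adjusted p = 2.92e-19) held 21 risen and 0 fallen members, and 22 risen when adjusted over the list alone, with ALD1 (2.81 ± 0.068) and WRKY46 (2.66 ± 0.068) beside PBS3 and CBP60G. Of 41 autophagy genes tested, 33 rose and 2 fell (34 and 2 adjusted over the list alone; median 0.48, adjusted p = 5.96e-14). ATG8H, one of the genes of the lipid-bound ATG8 proteins, rose from 13.8 to 48.6 FPKM (1.74 ± 0.061), ATG8A by 1.1 ± 0.053 and the kinase gene ATG1A by 1.26 ± 0.062. Senescence genes rose in 12 and fell in 2 of 16 cases (the same counts adjusted over the list alone; median 0.59, adjusted p = 2.58e-07), with NYE1 of chlorophyll breakdown at 1.69 ± 0.059 and the glutamine synthetase gene GLN1;4 at 1.65 ± 0.078. The list of carbon starvation and branched-chain amino acid breakdown had 15 of 20 members higher and 2 lower (16 and 2 adjusted over the list alone; median 0.23, adjusted p = 2.54e-05), including DIN2 (1.86 ± 0.090), DIN9 (1.21 ± 0.091) and BCKDH-E1A (0.91 ± 0.076). Peroxisomal β-oxidation and glyoxylate cycle genes rose in 17 and fell in 2 of 28 cases (19 and 3 adjusted over the list alone; median 0.21, adjusted p = 1.59e-04). ICL, which encodes isocitrate lyase of the glyoxylate cycle, rose from 9.39 ± 1.5 to 49.6 ± 5.3 FPKM (2.29 ± 0.091, adjusted p = 3.44e-10), and ACX2, CSY3 and ACX4 rose by 0.50 to 0.60 log2.

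Iron deficiency genes were higher in 14 and lower in 3 of 18 cases (the same adjusted over the list alone; median 0.81, adjusted p = 2.58e-07). The transcription factor genes BHLH100 (2.02 ± 0.047, adjusted p = 1.62e-12), BHLH39 (1.77 ± 0.063) and BHLH38 (1.74 ± 0.065) rose, as did F6H1 of coumarin synthesis (1.51 ± 0.049), and the iron store gene FER1 (−1.20 ± 0.057) fell together with FIT. All 11 anthocyanin and flavonoid genes fell (also adjusted over the list alone; median −0.65, adjusted p = 1.68e-05), for example FLS1 (−1.38 ± 0.072) and LDOX (−1.09 ± 0.13), and 10 of 11 aliphatic glucosinolate genes fell (the same adjusted over the list alone; median −0.82, adjusted p = 8.25e-07), for example IMD1 (−1.04 ± 0.038, adjusted p = 1.68e-10), CYP83A1 (−1.04 ± 0.059) and MAM1 (−0.96 ± 0.080). Of 10 auxin response genes 7 fell (the same adjusted over the list alone; median −0.56, adjusted p = 0.00179), among them IAA1 (−0.82 ± 0.079) and IAA3 (−0.77 ± 0.062). These 9 lists also passed with an estimated correlation between genes. Falls in 20 of 24 photosynthesis genes (median −0.25, adjusted p = 6.81e-07) and 15 of 18 photorespiration genes (median −0.19, adjusted p = 1.25e-04; counts the same adjusted over the list alone, with 1 photorespiration gene higher) did not, with an adjusted p = 0.363 and 0.276 with an estimated correlation. Single members fell even so, as the catalase gene CAT2 (AT4G35090) did from 363 ± 8.0 to 228 ± 7.9 FPKM (−0.67 ± 0.030, adjusted p = 1.15e-09), and as the light-harvesting gene LHCB2.3 did (−0.72 ± 0.044), whose reads may be shared with close paralogs.

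The other 11 lists did not pass in atg2-4. Of 23 peroxin genes 5 were higher and 1 lower (adjusted p = 0.383), among them PEX19A at 0.52 ± 0.057, and of 3 LON and DEG protease genes 1 was higher and 1, LON2, lower (adjusted p = 0.780). Oxidative stress genes moved both ways (8 higher and 7 lower of 16, adjusted p = 0.684), with the superoxide dismutase gene FSD1 at −1.92 ± 0.057, APX1 at −0.69 ± 0.045 and BAP1 at 1.15 ± 0.068. The ER unfolded protein response had 4 members higher and 8 lower of 12 (adjusted p = 0.126), among them BIP1 (−0.48 ± 0.033), whose reads may be shared with BIP2. Jasmonate genes had 5 higher and 9 lower of 23 (adjusted p = 0.248), with MYC2 at −0.66 ± 0.052, and proteasome subunits 9 and 3 of 37 (adjusted p = 0.158). Root markers went both ways, 4 up and 3 down of 18 (adjusted p = 0.870), with a median of 0.059 and a mean of −0.017, and PYK10 at −0.81 ± 0.031. Seed storage genes (3 higher and 6 lower of 12, adjusted p = 0.443), mitotic genes (0 and 4 of 11, adjusted p = 0.108), heat shock genes (3 and 2 of 10, adjusted p = 0.789) and phosphate starvation genes (3 and 1 of 8, adjusted p = 0.629) made up the rest.

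**Figure D3:**
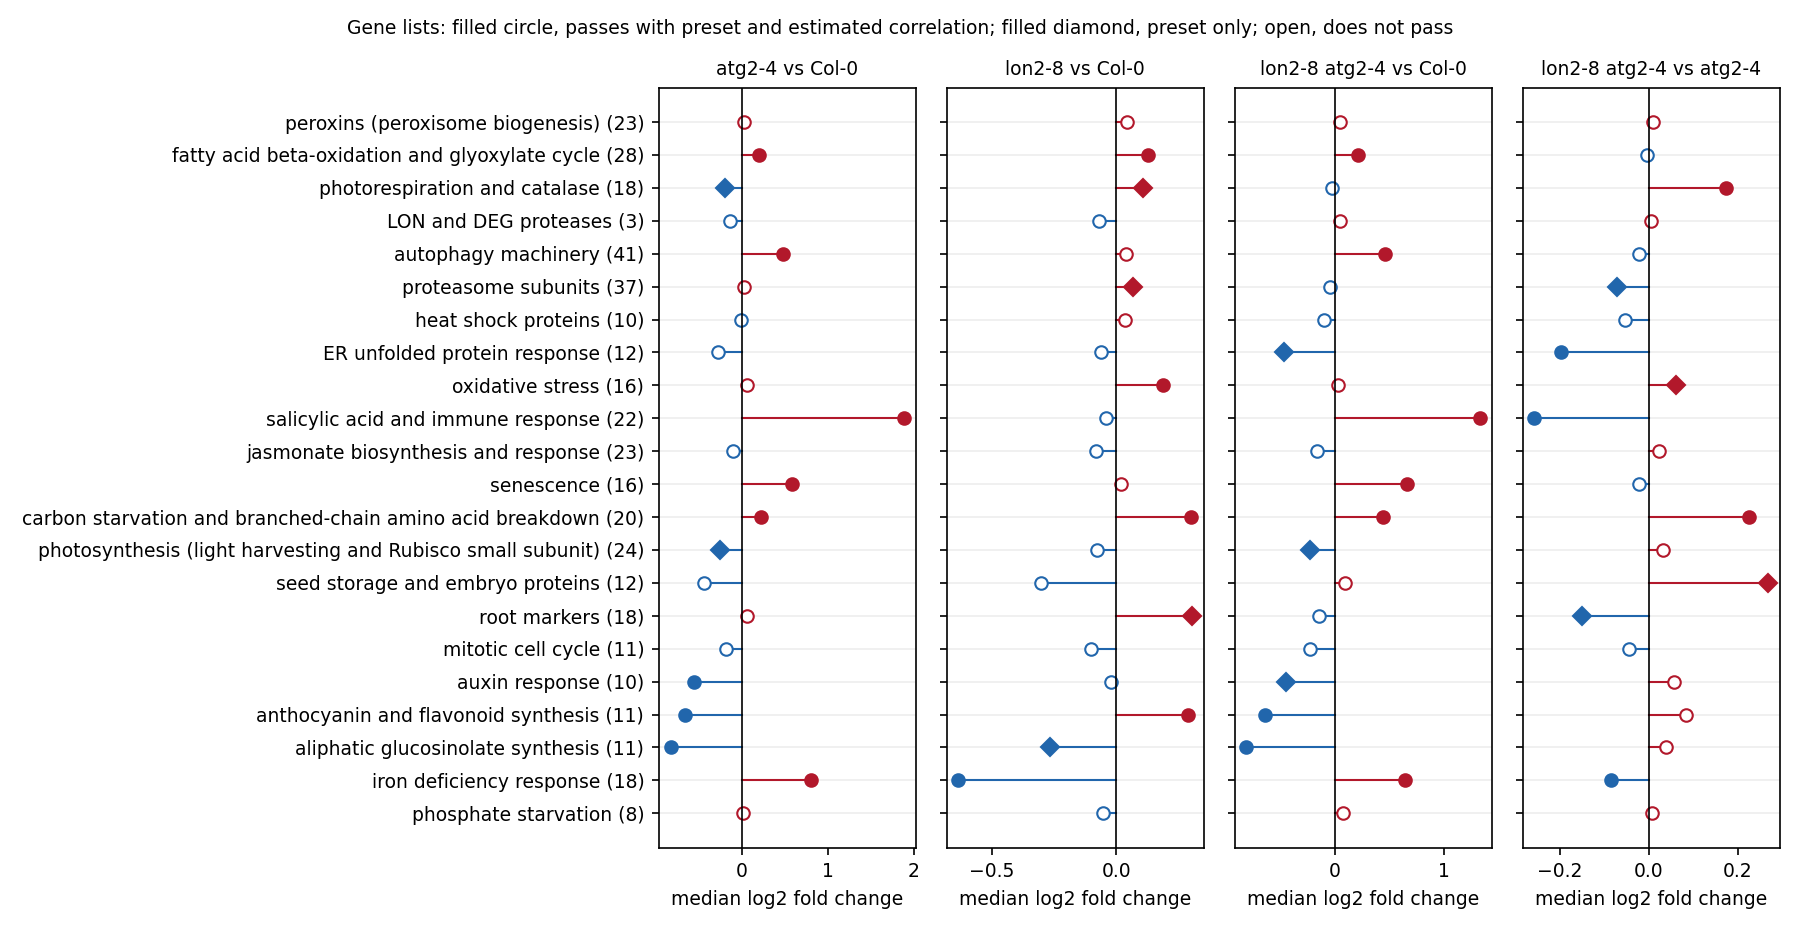
Median log2 fold change of the tested members of each of the 22 fixed gene lists in 4 comparisons. Filled circles passed (adjusted p under 0.05) with the preset and with an estimated correlation, diamonds with the preset correlation only, and open circles did not pass; the salicylic acid and immune response list stands highest, at 1.89 in atg2-4.

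The comparison of lon2-8 with Col-0 asks what a mutation of the peroxisomal Lon protease gene changes. Both genes that encode the enzymes particular to the glyoxylate cycle, ICL and MLS, rose (n = 3 libraries per genotype). ICL rose 4.94-fold, from 9.39 ± 1.5 to 46.4 ± 0.90 FPKM (2.2 ± 0.091 log2, adjusted p = 6.94e-09). MLS, which encodes malate synthase, the partner enzyme of ICL, rose 5.56-fold, to 10.7 ± 0.66 FPKM (2.00 ± 0.093, adjusted p = 1.69e-08). Iron deficiency genes fell, 15 of 18 of them, with IMA3, which encodes a mobile iron signal peptide, down to 3.03 from 7.91 FPKM (−1.14 ± 0.070). The cytosolic ascorbate peroxidase gene APX1 rose from 134 to 273 ± 10.3 FPKM (1.02 ± 0.045, adjusted p = 1.14e-08). In all 4779 of 20662 genes changed (23.1%), 1872 upward and 2907 downward, and 115 by at least 2-fold, of which 69 rose and 46 fell. The share of changed genes that were higher was 39.2%, and 58.3% when each library was centred on its median, so the balance of the many small changes depends on the scaling.

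AT1G73120, a gene without a named function, rose most, from 3.6 ± 0.49 to 61.2 ± 2.2 FPKM (3.76 ± 0.093, adjusted p = 1.79e-10). ELIP2, which encodes an early light-induced protein, rose 8.21-fold to 51.6 ± 1.3 FPKM (2.86 ± 0.11, adjusted p = 4.48e-09). The glucosyltransferase gene UGT74E2, used as a marker of hydrogen peroxide responses, rose from 1.35 to 8.32 ± 1.9 FPKM (1.97 ± 0.15, adjusted p = 8.62e-07), and the endoglucanase gene GH9B15 from 0.969 to 7.76 FPKM. AT4G12490, AT4G12500 and AT4G12495, neighbours whose reads may be shared, rose by 2.01, 1.93 and 2.15, and the unnamed locus AT1G64795 by 2.80. The largest falls were those of AT2G36255, to 3.34 ± 1.9 FPKM (−2.14 ± 0.26, adjusted p = 5.93e-05), and of the seed storage albumin genes SESA3 (−1.98 ± 0.26, adjusted p = 1.24e-04) and SESA2 (−1.5 ± 0.25), which are close paralogs. LSU2, a gene of the sulfur starvation response, fell from 15.8 ± 2.3 to 4.87 ± 0.50 FPKM (−1.51 ± 0.092, adjusted p = 1.53e-07), ESM1, which modifies glucosinolate breakdown, from 32.5 ± 1.7 to 11.4 ± 0.21, and the senescence regulator gene NAP from 8.27 ± 0.26 to 2.63 ± 0.23 (−1.35 ± 0.062, adjusted p = 1.51e-08). ACD6 (−1.45 ± 0.081), AT2G05705, AT2G30760 and AT5G59170 completed the 10 largest falls. All 20 of these genes also had an effect of lon2-8 that differed between the backgrounds by the interaction test. They were picked by their change in lon2-8, which is a part of the interaction and comes from the same libraries. The choice thus favoured these calls. AT2G36255 was listed at 0 in both groups with atg2-4 and could not fall there.

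Of the 22 lists, 9 passed, and 5 of them also with an estimated correlation. Of 28 β-oxidation and glyoxylate genes 13 rose and none fell (16 adjusted over the list alone; median 0.13, adjusted p = 5.54e-09), ICL and MLS ahead of ACX2 (0.44 ± 0.034) and ACX4 (0.33 ± 0.035). In the carbon starvation and branched-chain amino acid list 13 of 20 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.30, adjusted p = 4.05e-11), for example ASN1 (0.78 ± 0.055), BCAT2 (1.19 ± 0.090) and DIN10 (0.54 ± 0.027). Oxidative stress genes rose in 10 and fell in 1 of 16 cases (11 and 1 adjusted over the list alone; median 0.19, adjusted p = 7.86e-07), with the glutathione transferase genes GSTU25 (0.64 ± 0.065) and GSTU1 (0.61 ± 0.063) beside APX1. Anthocyanin and flavonoid genes had 4 of 11 members higher (5 adjusted over the list alone; median 0.29, adjusted p = 0.00131), among them CHS (0.55 ± 0.054) and FLS1 (0.34 ± 0.072). In the iron deficiency list 15 of 18 members fell and 1, FER1 (0.88 ± 0.057), rose, also adjusted over the list alone (median −0.63, adjusted p = 2.11e-09). BHLH100 fell from 10.6 to 5.08 FPKM (−0.93 ± 0.047, adjusted p = 3.14e-08), and OPT3, an iron transporter gene of the phloem, also fell (−0.71 ± 0.036).

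The 4 lists that passed only with the preset correlation were the root markers, photorespiration, the proteasome and glucosinolates. Root markers had 9 members higher and 1 lower of 18, also adjusted over the list alone (median 0.31, adjusted p = 2.23e-05; adjusted p = 0.267 with an estimated correlation), with the glucosidase gene PYK10 at 0.63 ± 0.031. The rise of these markers ran alongside the fall of the iron deficiency genes, many of which are expressed in roots. Photorespiration genes rose in 9 and fell in 1 of 18 cases (12 and 2 adjusted over the list alone; median 0.11, adjusted p = 9.24e-05; adjusted p = 0.267 with an estimated correlation, and 0.204 after quantile normalization). CAT2, which fell in atg2-4, rose from 363 to 515 ± 1.8 FPKM (0.50 ± 0.030, adjusted p = 1.25e-07). Of 37 proteasome subunits only 5 rose, also adjusted over the list alone (median 0.068, adjusted p = 1.17e-05; adjusted p = 0.185 with an estimated correlation), for example PAD2 (0.33 ± 0.048). Glucosinolate genes fell in 7 of 11 cases, also adjusted over the list alone (median −0.27, adjusted p = 2.30e-04; adjusted p = 0.0599 with an estimated correlation), among them CYP83A1 (−0.60 ± 0.059) and MYB28 (−0.50 ± 0.056).

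The remaining 13 lists did not pass in lon2-8. Of 41 autophagy genes 2 rose, ATG8H (0.53 ± 0.061) among them, and 4 fell, such as ATG4A (−0.56 ± 0.043), with a median of 0.039 and a mean of −0.0022 (adjusted p = 0.393). Peroxins had 1 member higher, PEX11E (0.20 ± 0.045), and 1 lower, PEX17 (−0.48 ± 0.077), of 23 (adjusted p = 0.311). Salicylic acid and immune genes went both ways, with WRKY70 (−1.0 ± 0.070) and CBP60G (−0.46 ± 0.051) lower and PR1 (0.98 ± 0.098) and PR2 (0.51 ± 0.10) higher (2 higher and 4 lower of 22, adjusted p = 0.737). The senescence list also split, 6 higher and 3 lower of 16 (median 0.020, mean −0.038, adjusted p = 0.294), with SAG21 (0.49 ± 0.041) up and ORE1 (−0.74 ± 0.046), WRKY53 (−0.69 ± 0.067) and NAP down. Photosynthesis genes were lower in 11 and higher in 3 of 24 cases (adjusted p = 0.0940), and seed storage genes lower in 4 of 12 (adjusted p = 0.0913). No auxin response gene passed (GH3.5 was nearest, adjusted p = 0.0827). In the heat shock list 3 of 10 rose, for example HSP17.6A (0.65 ± 0.12), and the jasmonate list had AOS lower (−0.50 ± 0.047) and LOX2 higher (0.47 ± 0.064; 5 higher and 8 lower of 23, adjusted p = 0.770). The ER unfolded protein response (adjusted p = 0.273), LON and DEG proteases (adjusted p = 0.173), mitotic (adjusted p = 0.279) and phosphate starvation genes (adjusted p = 0.638) had 1 to 4 members passing each.

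**Figure D4:**
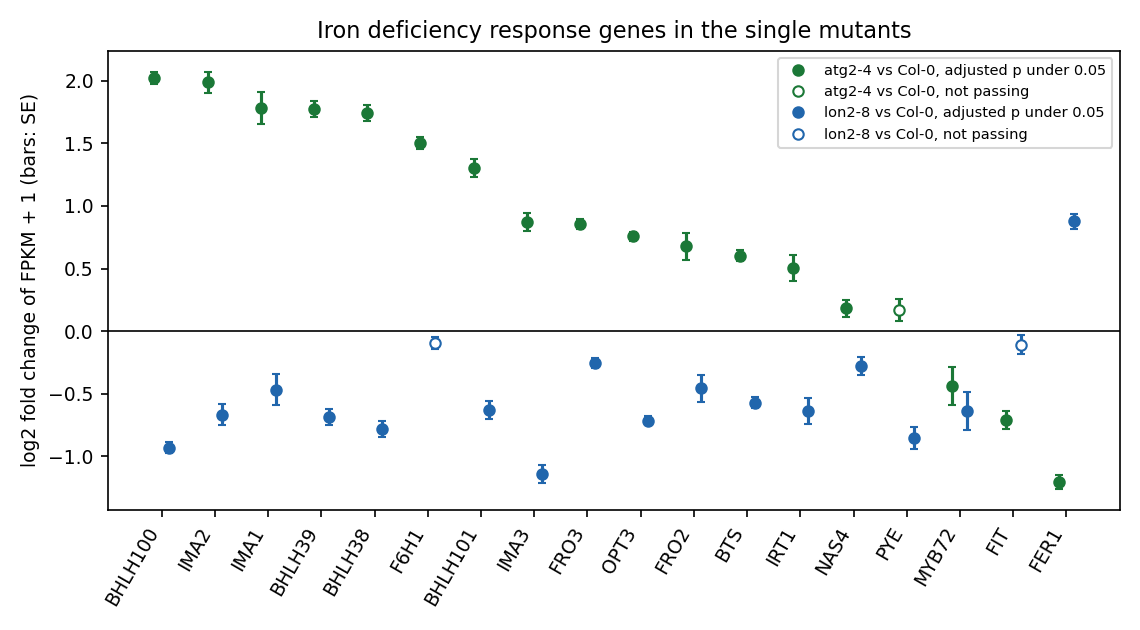
Log2 fold change against Col-0, with its standard error, of the 18 tested iron deficiency genes in atg2-4 (green) and lon2-8 (blue); open symbols did not pass. Most members lie above 0 in atg2-4 and below 0 in lon2-8, and FER1 lies the other way.

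The comparison of the double mutant with Col-0 asks what both mutations give together. Salicylic acid and immune genes again rose most as a group, 21 of 22, with FMO1, which encodes an enzyme of systemic immunity, at 3.87 ± 0.12 and CBP60G at 3.35 ± 0.051 (adjusted p = 2.54e-14; n = 3 libraries per genotype). ICL rose further than in either single mutant, to 81.5 ± 0.63 FPKM (3.00 ± 0.091, adjusted p = 2.19e-11), whereas MLS was at 2.09 ± 0.29 FPKM, against 1.92 ± 0.088 in Col-0 (adjusted p = 0.5004). NBR1 rose by 1.24 ± 0.030 (adjusted p = 2.85e-12). In all 10753 genes changed (52.0%), 4541 upward and 6212 downward, and 875 by at least 2-fold, of which 702 rose and 173 fell. The share that were higher was 42.2%, and 51.2% after median-centring. AT1G26240 (8.41 ± 0.11), AT1G26390 (7.86 ± 0.059), CYP82C2 (6.38 ± 0.092) and GLP9, at 488 ± 14 FPKM, were among the 10 largest rises, as was AT3G28510, an AAA-type ATPase gene, at 75.0 ± 0.81 FPKM against 0.375 in Col-0. Among the 10 largest falls, AT2G36255 was again listed at 0 in all double mutant libraries, and IMPA-1 (−2.50 ± 0.049), LON2 and the galactosidase gene BGAL8, from 35.0 ± 1.3 to 6.78 ± 0.27 FPKM (−2.21 ± 0.069), followed AT5G33355, CYP81D11 and AT3G59930.

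Of the 22 lists, 11 passed. The calls held with an estimated correlation for salicylic acid and immune genes (21 of 22 higher, also adjusted over the list alone; median 1.33, adjusted p = 3.45e-16), autophagy (33 higher and 2 lower of 41; 34 and 2 adjusted over the list alone; median 0.46, adjusted p = 1.20e-12) and senescence (11 and 1 of 16; 12 and 1 adjusted over the list alone; median 0.66, adjusted p = 1.08e-07). ATG8H (1.5 ± 0.061), ATG11 (0.81 ± 0.042) and SAG21 (1.16 ± 0.041) were among the risen genes. They also held for carbon starvation and branched-chain amino acid breakdown, where 18 of 20 rose and 1 fell (also adjusted over the list alone; median 0.44, adjusted p = 3.63e-09). SEN1 (AT4G35770; 1.51 ± 0.062) and BCKDH-E1A (1.58 ± 0.076) were among them. β-Oxidation genes rose in 18 and fell in 3 of 28 cases (also adjusted over the list alone; median 0.21, adjusted p = 7.98e-05), with ACX4 at 0.64 ± 0.035. Iron deficiency genes were higher in 13 and lower in 2 of 18 cases, also adjusted over the list alone (median 0.64, adjusted p = 3.05e-06), with BHLH100 at 1.97 ± 0.047. Glucosinolate genes fell in 10 of 11 cases (median −0.81, adjusted p = 1.92e-05) and anthocyanin genes in 10 of 11 (median −0.64, adjusted p = 2.66e-04), both also adjusted over the list alone, for example MYB29 (−1.28 ± 0.12) and FLS1 (−1.48 ± 0.072).

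The falls of photosynthesis genes (19 of 24, adjusted p = 1.17e-05), auxin response genes (6 of 10, adjusted p = 0.0115) and ER unfolded protein response genes (8 lower and 3 higher of 12, adjusted p = 0.0152) passed as lists only with the preset correlation, and with an estimated correlation had adjusted p = 0.405, 0.0645 and 0.227; their counts were the same adjusted over the list alone. GH3.3 (−1.0 ± 0.095) and BIP1 (−0.74 ± 0.033) fell by their own adjusted p. Photorespiration genes had 3 members higher and 4 lower of 18 in the double mutant (adjusted p = 0.713), and CAT2 fell (−0.37 ± 0.030). Seed genes moved both ways, EM6 up (1.64 ± 0.17) and SESA4 down (−1.05 ± 0.11), with a median of 0.091 and a mean of −0.0052 (adjusted p = 0.718), and of the root markers 6 of 18 fell (adjusted p = 0.110). Oxidative stress (adjusted p = 0.347), peroxin (adjusted p = 0.192) and jasmonate genes (adjusted p = 0.158) did not pass as lists, though FSD1 fell (−1.73 ± 0.057) and PEX19A rose (0.54 ± 0.057). Among mitotic genes 6 of 11 fell (adjusted p = 0.0974), and the proteasome, heat shock, LON and DEG protease and phosphate starvation lists had adjusted p = 0.653 to 0.770.

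The comparison of the double mutant with atg2-4 asks what lon2-8 does in the atg2-4 background. Beside LON2 (−2.01 ± 0.064, adjusted p = 4.56e-09) and MAD1 (−1.59 ± 0.061, adjusted p = 2.60e-08), few genes changed much (n = 3 libraries per genotype). The seed lipid body gene OLEO1 rose from 2.76 to 8.07 ± 1.8 FPKM (1.25 ± 0.18, adjusted p = 9.40e-04), and PER1, which encodes a seed peroxiredoxin, from 3.74 ± 0.89 to 11.4 ± 1.0 (1.41 ± 0.14, adjusted p = 8.13e-05). Immune genes fell modestly, with ALD1, of pipecolate synthesis, at −0.87 ± 0.068 (adjusted p = 1.04e-05). SEN1, a gene induced in darkness, rose from 34.4 to 66.9 FPKM (0.94 ± 0.062, adjusted p = 3.30e-06). In all 1835 of 20662 genes changed (8.88%), 918 upward and 917 downward, and 22 by at least 2-fold, of which 17 rose and 5 fell. The share that were higher was 50.03%, and between 46.1% with voom and 56.3% after median-centring. The count depended on the libraries, at 1069 without atg2-4 library 3, 1090 without double mutant library 2 and 1064 without double mutant library 3. THA1, a threonine aldolase gene, rose from 1.08 to 3.87 ± 0.016 FPKM (1.23 ± 0.095, adjusted p = 1.03e-05), and OLEO2 (1.15 ± 0.16) and the peroxidase gene PRX52 (1.12 ± 0.13, adjusted p = 2.36e-04) were also among the 10 largest rises. The unnamed locus AT3G06355 went from 152 ± 16 to 352 ± 5.1 FPKM. The rise of the microRNA locus MIR160c (adjusted p = 0.0135) was lost without atg2-4 library 2 (adjusted p = 0.0518), without atg2-4 library 3 (adjusted p = 0.0567) or without double mutant library 1 (adjusted p = 0.0518). Among the falls, AT1G64795, which rose in lon2-8, went from 45.7 ± 1.9 FPKM to 0.385 times that level (−1.33 ± 0.10, adjusted p = 9.28e-06). AT4G33720, of the family of PR1, fell from 23.0 ± 1.9 to 11.1 ± 0.80 FPKM (−0.99 ± 0.10, adjusted p = 9.15e-05; adjusted p = 0.121 with a pseudocount of 0.1).

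Of the 22 lists, 9 passed, and 5 of them also with an estimated correlation. Photorespiration genes rose in 13 of 18 cases, also adjusted over the list alone (median 0.17, adjusted p = 1.17e-13), with CAT2 at 0.30 ± 0.030 and the glycolate oxidase gene GOX1 at 0.24 ± 0.033. Carbon starvation genes rose in 11 and fell in 1 of 20 cases (14 and 3 adjusted over the list alone; median 0.22, adjusted p = 3.00e-09), among them DIN10 (0.51 ± 0.027), BCKDH-E1A (0.67 ± 0.076) and PRODH1 (0.45 ± 0.036). Salicylic acid and immune genes fell in 11 of 22 cases (13 adjusted over the list alone; median −0.26, adjusted p = 6.18e-09), for example AED1 (−0.78 ± 0.073) and SARD1 (−0.53 ± 0.072), from the raised levels of atg2-4. ER unfolded protein response genes fell in 7 of 12 cases (11 adjusted over the list alone; median −0.20, adjusted p = 1.35e-07), among them CNX1 (−0.25 ± 0.032) and HSP90.7 (−0.19 ± 0.031). The iron deficiency list was lower (adjusted p = 0.00813) by a median of only −0.086, with 3 of 18 members passing (also adjusted over the list alone), BHLH101 (−0.51 ± 0.071), OPT3 and BTS.

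With the preset correlation alone, seed storage genes rose (4 of 12; 6 adjusted over the list alone; median 0.27, adjusted p = 0.00179; adjusted p = 0.321 with an estimated correlation), OLEO1, OLEO2 and EM6 (1.07 ± 0.17) among them. Root markers were lower in 3 and higher in 1 of 18 cases (6 and 1 adjusted over the list alone; median −0.15, adjusted p = 0.0231; adjusted p = 0.519 with an estimated correlation), a call that also ended without atg2-4 library 3 (adjusted p = 0.149) or without double mutant library 2 (adjusted p = 0.0501). LRX1, which encodes a root hair cell wall protein, fell (−0.41 ± 0.091). That call was lost without atg2-4 library 3 (adjusted p = 0.0618) or without double mutant library 3 (adjusted p = 0.0634). The proteasome list was lower (median −0.071, adjusted p = 1.01e-04; adjusted p = 0.233 with an estimated correlation) and 1 of 37 members, RPN6 (−0.15 ± 0.041), passed over all genes and none adjusted over the list alone. The call of RPN6 was lost under 10 alternatives (adjusted p = 0.0514 to 0.142), the removal of any Col-0 library or of library 2 or 3 of either group compared among them. The oxidative stress list was higher (adjusted p = 0.0237; adjusted p = 0.267 with an estimated correlation), with ZAT10 (0.58 ± 0.054) and ZAT12 up and CSD1 down of 16 members (3 and 1 adjusted over the list alone), and did not pass without atg2-4 library 1 (adjusted p = 0.0985) or after quantile normalization (adjusted p = 0.0519). β-Oxidation genes did not pass (adjusted p = 0.128; 5 of 28 higher, median −0.0048 although the test pointed upward), with ICL at 0.71 ± 0.091 (adjusted p = 4.84e-04) and MLS at 0.14 ± 0.093 (adjusted p = 0.394). No anthocyanin gene passed (DFR was nearest, adjusted p = 0.0572), and autophagy genes had 2 members higher and 1 lower of 41 (adjusted p = 0.419). The other 10 lists that did not pass had adjusted p = 0.192 to 0.906. At most 4 of their members passed in a direction, such as HSP17.6A (−0.65 ± 0.12) and AOC2 (−0.34 ± 0.052), both lower.

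The comparison of the double mutant with lon2-8 gives the effect of atg2-4 in the lon2-8 background. Its strongest rises by adjusted p were AT1G26390, from 3.29 to 356 FPKM, AT5G38910 (6.93 ± 0.064), AT4G38060, from 14.0 ± 0.47 to 119.8 ± 2.5 FPKM (3.01 ± 0.035, adjusted p = 4.66e-15), AT3G28510 and AT2G29220 (n = 3 libraries per genotype). The strongest falls were AT5G33355 (−3.99 ± 0.057), IMPA-1 (−2.45 ± 0.049), the TRAF-like gene AT5G26280, from 224 ± 7.3 to 67.9 ± 1.1 FPKM, HEMA1, of chlorophyll and heme synthesis, from 127 ± 1.7 to 36.7 ± 0.43 FPKM (−1.77 ± 0.041, adjusted p = 1.95e-12), and AT3G59930. In all 10305 genes changed (49.9%), 5220 upward and 5085 downward, and 853 by at least 2-fold. The share that were higher was 50.7%, and 43.2% after quantile normalization. Of the 22 lists 13 passed, and 5 also with an estimated correlation. These were salicylic acid and immune genes (21 of 22 higher, median 1.51, adjusted p = 4.47e-15), autophagy (33 higher and 1 lower of 41, median 0.50, adjusted p = 5.63e-12), senescence (12 and 2 of 16, adjusted p = 1.46e-06), iron deficiency (15 and 2 of 18, median 1.15, adjusted p = 6.81e-09) and, downward, anthocyanin genes (11 of 11, adjusted p = 3.05e-06). Adjusted over the list alone, these counts differed only for autophagy (35 and 1). ORE1 (1.61 ± 0.046) and NAP (1.46 ± 0.062), both lower in lon2-8, were higher in the double mutant, as was BHLH100 (2.90 ± 0.047), while FER1 (−2.04 ± 0.057), APX1 (−1.78 ± 0.045) and MLS (−1.92 ± 0.093) fell. Root markers fell in 12 of 18 cases (13 adjusted over the list alone; median −0.56, adjusted p = 3.09e-04; adjusted p = 0.345 with an estimated correlation), beside rises of the iron genes. The other 7 passed only with the preset correlation. With an estimated correlation they gave adjusted p = 0.126 for carbon starvation, 0.481 for photorespiration, 0.334 for the proteasome, 0.126 for the ER unfolded protein response, 0.503 for photosynthesis, 0.0526 for auxin response and 0.126 for glucosinolate genes. Quantile normalization also ended the calls of photorespiration (adjusted p = 0.102) and photosynthesis (adjusted p = 0.136).

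The interaction asks whether lon2-8 acts differently in the Col-0 and the atg2-4 background. The glyoxylate cycle showed such a difference, with MLS at 1.92 ± 0.088 FPKM in Col-0 and 10.7 ± 0.66 in lon2-8, but at 1.80 ± 0.31 in atg2-4 and 2.09 ± 0.29 in the double mutant (interaction −1.86 ± 0.13 log2, adjusted p = 2.35e-06; n = 3 libraries per genotype). ICL, raised in both single mutants, rose by less in the double mutant than the sum of both effects (−1.49 ± 0.13, adjusted p = 1.08e-05). AT1G73120 stood at 3.6, 3.22, 61.2 and 4.54 FPKM in Col-0, atg2-4, lon2-8 and the double mutant (−3.36 ± 0.13, adjusted p = 2.81e-08). In all 2723 genes had an interaction (13.2%), 1466 with a positive and 1257 with a negative sign, 144 of them of at least 2-fold. The positive share was 53.8%, and 41.1% after each library was centred on its median. Of the genes with the smallest adjusted p, the mitochondrial carrier gene DIC2 (1.35 ± 0.059, adjusted p = 8.26e-08) and the stress transcription factor genes ERF104 (1.06 ± 0.060), AT5G51190 (1.49 ± 0.093) and WRKY33 (0.92 ± 0.057) fell in lon2-8 against Col-0. In the double mutant against atg2-4, DIC2, ERF104 and AT5G51190 rose, while WRKY33 was at 59.3 against 55.7 FPKM (adjusted p = 0.206). COL1 completed the positive set (0.84 ± 0.052). The negative set was AT1G64795 (−4.13 ± 0.14), AT1G73120, EARLI1 (−1.56 ± 0.075), AT5G26280 (−1.01 ± 0.050) and the cadmium resistance gene PCR2 (−1.13 ± 0.063).

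Of the 22 lists, 10 passed for the interaction, and 4 of them also with an estimated correlation. β-Oxidation and glyoxylate genes had 8 of 28 members with a negative interaction (11 adjusted over the list alone; median −0.15, adjusted p = 3.03e-06), ACX2 (−0.32 ± 0.047) among them. Iron deficiency genes had 11 positive and 1 negative of 18 (also adjusted over the list alone; median 0.42, adjusted p = 1.68e-06), with IMA3 at 1.03 ± 0.099 and FER1 at −0.83 ± 0.080. Glucosinolate genes had 6 positive of 11 (9 adjusted over the list alone; median 0.30, adjusted p = 2.23e-05), among them BCAT4 (0.81 ± 0.091), and immune genes 1 positive and 6 negative of 22 (1 and 8 adjusted over the list alone; median −0.29, adjusted p = 3.00e-04), among them ALD1 (−1.04 ± 0.096) and PR1 (−0.77 ± 0.14). With the preset correlation alone, root markers (median −0.41, adjusted p = 1.90e-07; adjusted p = 0.180 with an estimated correlation), proteasome subunits (adjusted p = 1.39e-09; 0.0647 with an estimated correlation), oxidative stress genes (adjusted p = 4.17e-04; 0.0954) and the ER unfolded protein response (adjusted p = 0.00359; 0.159) had negative interactions. PRP3 (−1.06 ± 0.15), APX1 (−1.08 ± 0.064) and BIP3 (−1.23 ± 0.18) belonged to these. Positive ones were found for seed storage genes (median 1.21, adjusted p = 3.39e-04; 0.261 with an estimated correlation), with OLEO1 at 1.77 ± 0.25, and photosynthesis genes (adjusted p = 0.0403; 0.686 with an estimated correlation), with RBCS2B at 0.59 ± 0.049. The photosynthesis call was also lost after median-centring (adjusted p = 0.149), without a filter (adjusted p = 0.0537) and with the library number as a block (adjusted p = 0.0527). Without library 2 or 3 of Col-0, 1 or 3 of atg2-4, 1 or 2 of lon2-8 or 3 of the double mutant it was lost as well (adjusted p = 0.0719 to 0.184). Of the other 12 lists, which did not pass, anthocyanin (adjusted p = 0.0584) and heat shock genes (adjusted p = 0.0601) came nearest. The senescence list did not pass (adjusted p = 0.672) although NAP did (1.23 ± 0.088).

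The effects of lon2-8 in both backgrounds were set side by side from comparisons that share no library. Of 4779 genes changed in lon2-8 against Col-0 and 1835 in the double mutant against atg2-4, 362 were higher in both (83.2 expected if independent), 270 lower in both (129 expected) and 263 changed in opposite directions. By the rises and falls counted in each comparison, fewer than 263 genes would be expected in opposite directions if independent. Changes in opposite directions were thus also in excess, though by less than those in the same direction. An excess over independence is therefore not by itself a shared effect of lon2-8. The log2 fold changes correlated at r = 0.144 (rho = 0.111) across genes, which are not independent replicates. The SD of the log2 fold changes over all tested genes, corrected for their error, was 0.218 in lon2-8 against Col-0 and 0.138 in the double mutant against atg2-4. LON2 and MAD1 had larger falls in the atg2-4 background. The effects of atg2-4 in the Col-0 and lon2-8 backgrounds were more alike, with 3436 genes higher in both (1112 expected), 3485 lower in both (1384 expected), 290 opposite and r = 0.844 across genes.

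**Figure D5:**
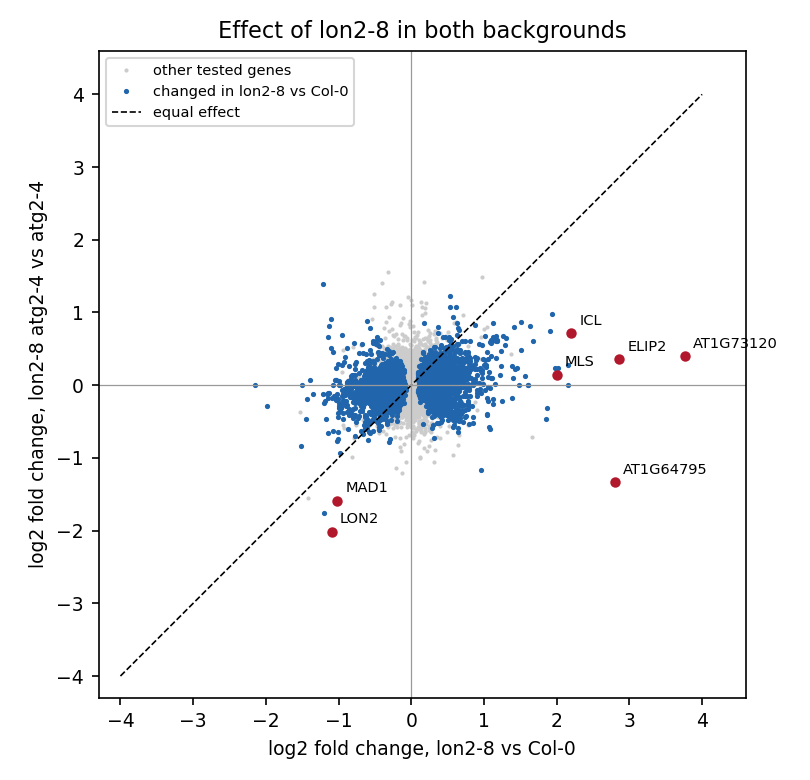
Log2 fold change of each tested gene in lon2-8 against Col-0 (horizontal) and in the double mutant against atg2-4 (vertical), with genes changed in lon2-8 in blue and equal effects on the dashed line. ICL, MLS, ELIP2 and AT1G73120 lie far below the line, and LON2 and MAD1 have larger falls in the atg2-4 background.

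The authors' deposited table lists 7800 genes as changed in atg2-4 (4803 up and 2997 down), 4010 in lon2-8 (2198 and 1812) and 8653 in the double mutant (5080 and 3573) against Col-0, at a false discovery rate under 0.01. For the double mutant against atg2-4 the authors' deposited table lists 2685 genes (1437 up, 1235 down and 13 with no direction) at a rate under 0.05. The direction column beside the authors' FPKM values marks fewer for this comparison, 810 up and 660 down, as many as the 1470 genes with a rate under 0.01. Of the listed genes that were also tested here, limma called 96.3%, 88.0%, 96.3% and 64.0% in these 4 comparisons, and 0 of them in the opposite direction. Of the limma calls, at an adjusted p under 0.05 in every comparison, the authors' deposited table lists 68.5%, 70.5%, 70.5% and 88.8%. In the authors' deposited table the log2 fold changes of LON2 were −0.22, −1.16, −2.44 and −2.22, and the test behind these calls is not given in the sources used here.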

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

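The interaction tests were planned, and the tests on shuffled residuals, selection, batch labels, root share, mixed seedlings and a second change near LON2 were chosen after the results were seen. Every result here stands out because the effect of lon2-8 differed between the Col-0 and the atg2-4 background by the interaction test of limma. This held for 2723 genes. When the 12 libraries were assigned to 4 groups of 3 at random, 1 of 100 splits, the real one, gave as many genes, and the highest of the other splits gave 96. Those splits mix libraries with and without atg2-4, which widens the spread within groups, so they do not decide whether chance gave the count. In 100 draws that kept the main effects of both mutations and shuffled the residuals over the libraries, the highest count was 2. Random differences between single libraries thus do not account for the real count. Shifts shared by the 3 libraries of a genotype were not in the draws, so they cannot be excluded as its source.

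The genes singled out by the smallest adjusted p were DIC2 (1.35 log2), ERF104 (1.06), COL1 (0.84), WRKY33 (0.92) and AT5G51190 (1.49) with a positive interaction, and AT1G64795 (−4.13), AT1G73120 (−3.36), EARLI1 (−1.56), AT5G26280 (−1.01) and PCR2 (−1.13) with a negative one. LON2 itself had an interaction of −0.92. All 20 genes named for their large change in lon2-8 had an interaction. That change is itself a part of the interaction and comes from the same libraries, so the choice of these genes favoured the calls. The lists with an interaction had median values of −0.15 for β-oxidation and glyoxylate genes, −0.16 for proteasome subunits, −0.095 for the ER unfolded protein response, −0.19 for oxidative stress, −0.29 for salicylic acid and immune response, −0.41 for root markers, 0.091 for photosynthesis, 1.21 for seed storage, 0.30 for glucosinolates and 0.42 for iron deficiency. With an estimated correlation 4 of these passed (β-oxidation, immune response, glucosinolates and iron deficiency), and the adjusted p of the others was 0.0647 for the proteasome, 0.159 for the ER unfolded protein response, 0.0954 for oxidative stress, 0.180 for root markers, 0.686 for photosynthesis and 0.261 for seed storage.

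The first pattern weighed is that lon2-8 changed expression less where atg2-4 was present. Genes picked for a large effect in noisy data would show a smaller one elsewhere, but over all tested genes, corrected for the error of the first effect, the slope of the effect in the atg2-4 background on that in Col-0 was 0.123 (0.107 to 0.139 with a library left out), against 0.981 to 1.02 in 100 simulations of equal effects. The slope also drops where the effects differ in direction, so it does not measure size. The SD of the effects over all tested genes, corrected for error, was 0.138 in the atg2-4 background and 0.218 in Col-0, a ratio of 0.635 (0.623 to 0.668 with a library left out). No gene was picked for either value, which argues against selection as the cause. A larger spread between libraries in the groups with atg2-4 was excluded by a ratio of the median SD within groups of 1.03 (0.966 to 1.1). Samples grown or harvested apart stay open, since 0 labels name a batch and each genotype is a single group. The biological explanation, that impaired autophagy may remove or already contain much of the response to lon2-8, was not tested beyond the interaction itself.

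The second pattern is that iron deficiency genes were higher in atg2-4 and lower in lon2-8, as 13 of 18 members were. This count is close to the 11.7 expected if the calls in both mutants were independent. In 50 draws of unchanged groups it was at most 0. Those draws hold no changed gene and so give few calls of any kind, and their 0 does not bear on opposite movement. The root markers had a median of 0.31 in lon2-8 (0.24 to 0.36 with a library left out), opposite to the iron genes at −0.63. In atg2-4 their median was 0.059. Single markers differed, from −0.22 to 0.65 in lon2-8 and from −0.81 to 0.39 in atg2-4. Where in the seedling the iron genes are expressed was not measured. The values in lon2-8 thus argue against a different share of root tissue only for iron genes expressed mainly in roots. Those in atg2-4 do not settle it, since the markers went both ways. In the direct comparison of lon2-8 with atg2-4 the list had a median of −1.32 (−1.35 to −1.30 with a library left out). It passed there (adjusted p = 1.42e-09 from limma, and 0.00139 with an estimated correlation). The difference between the 2 mutants thus does not rest on chance values of the shared Col-0 libraries. That comparison cannot show on which side of Col-0 either mutant lies, so such values stay open for the opposite directions. Library scaling is excluded by a smallest list median of 0.588 in size over 3 scalings. A response of iron regulation itself remains a hypothesis, and whether it may follow from iron content was not measured.

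The third pattern is that LON2 and MAD1 were lower in the double mutant than in lon2-8, although both carry the same lon2-8 mutation. Library scaling is excluded, since the interaction nearest to 0 over 3 scalings and both genes was −0.60. Seedlings without the mutation mixed into the lon2-8 libraries may raise both genes: the share needed was 29.7% from LON2 (28.4 to 31.8 with a library left out) and 23.5% from MAD1 (21.8 to 24.5). These differ by more than their ranges, so the bound first set was met, but it was replaced because differing shares exclude only a mix in which the mutant line keeps 1 level of each gene in both backgrounds, and that was not tested. A second sequence change near LON2 carried with lon2-8 was not decided by any value: 236 tested genes lie between LON2 and MAD1, and a change present in both lines would not by itself make them differ.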

How the results depend on the processing

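Voom on recovered fragments and the scalings of the lists were chosen after the data were seen; the other alternatives were planned. No named gene or list that passed reversed its direction under any alternative run.

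The counts of changed genes stayed within 1.5 times the reported ones under both pseudocounts, all filters, quantile normalization, median-centring, array weights, voom and the libraries of the compared groups alone. With a limit of 2-fold they were 810, 115, 875, 22, 853 and 144 for atg2-4, lon2-8 and the double mutant against Col-0, the double mutant against atg2-4 and against lon2-8, and the interaction, since this limit by construction removes smaller changes. Leaving out 1 library gave 8833 to 9996, 3548 to 4864, 9706 to 10820, 1064 to 1856, 9228 to 10378 and 2094 to 2753 genes in the same order. For the double mutant against atg2-4 the count was 1069 without atg2-4 library 3, 1090 without double mutant library 2 and 1064 without double mutant library 3; fewer libraries give less power, and the cause beyond that was not tested. Voom gave 10484, 5659, 11281, 2553, 10799 and 3424.

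With an estimated correlation fewer lists passed in every comparison. Against Col-0 the number went from 11 to 9 (atg2-4), from 9 to 5 (lon2-8) and from 11 to 8 (double mutant). It went from 9 to 5 for the double mutant against atg2-4, from 13 to 5 against lon2-8 and from 10 to 4 for the interaction. The cause was not tested. Leaving out 1 library gave 11 lists in every case for atg2-4 and for the double mutant against Col-0, and 9 to 11 in lon2-8, 8 to 11 for the double mutant against atg2-4, 13 to 14 against lon2-8 and 9 to 12 for the interaction.

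Of 63 list calls, 36 passed under every alternative, 27 were lost with an estimated correlation, 3 with 1 library left out and 5 under another alternative; a call can be lost in several ways. Of 551 calls of named genes, 480 passed under every alternative, 64 were lost with 1 library left out and 46 under another alternative, of which 5 with voom; the cause was not tested.

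With the library number as a replicate block, 9901, 4578, 10613, 1639, 10180 and 2540 genes changed. The block ended the call of the photosynthesis list for the interaction (adjusted p = 0.0527, limma) and of 13 named genes, and no other list call. The numbers share no pairing in the labels: the 18 pairs of libraries with the same number in different groups correlated at −0.057 to 0.049 across genes, 0 of them over 0.1, and 6 of 12 libraries correlated best with their own number.

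A test by DESeq2 or edgeR was planned only for deposited counts and was not run; the recovered fragments were tested with voom. The interaction has no alternative with only the groups compared, because it uses all 4.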

Other observations

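The 5 further lists and their tests were chosen after the results were seen. The same libraries served for the choice and for the tests, so the choice favoured these calls. The p-values of these lists thus describe the changes and are not independent evidence for them. They were adjusted over these 5 lists and all comparisons, apart from the fixed lists. Hypoxia genes rose in both single mutants and in the double mutant. Of 14 members 9 rose in atg2-4 (adjusted p = 7.38e-05 from limma; 0.0950 with an estimated correlation), 9 rose and 1 fell in lon2-8 (adjusted p = 2.74e-09; 0.0230), and 13 rose in the double mutant against Col-0 (adjusted p = 1.80e-08; 0.0274). Against atg2-4, 12 rose in the double mutant (adjusted p = 1.16e-15; 0.00871). Against lon2-8, 9 were higher and 2 lower, and the list passed only with the preset correlation (adjusted p = 0.00855; 0.207), as did its negative interaction (adjusted p = 0.0340; 0.283). HB1, a hemoglobin gene, rose by 1.54 ± 0.064 in atg2-4, 1.02 ± 0.064 in lon2-8 and 2.21 ± 0.064 in the double mutant, and the oxygen sensor genes PCO1 and PCO2 by 1.64 ± 0.088 and 1.78 ± 0.058 in the double mutant. ADH1, which encodes alcohol dehydrogenase, rose in atg2-4 (0.84 ± 0.12) and the double mutant (1.47 ± 0.12), with an adjusted p = 0.599 in lon2-8.

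Sulfur starvation genes were lower with lon2-8 in both backgrounds. LSU2, a member of this list, was already named above among the largest falls in lon2-8, which favoured the call there. In lon2-8 7 of 12 fell and 2 rose (adjusted p = 9.10e-06; 0.00871 with an estimated correlation), with LSU2 at −1.51 ± 0.092, SDI2 at −1.08 ± 0.069 and the sulfate reduction gene APR3 at −1.03 ± 0.042, and in the double mutant 7 were lower than in atg2-4 (adjusted p = 2.45e-08; 0.00559). Their interaction was positive for 7 and negative for 1 (adjusted p = 0.00863; 0.0507 with an estimated correlation). Type-A cytokinin response regulators rose in lon2-8, 7 of 9 (adjusted p = 1.97e-07; 0.0109), led by ARR7 (1.08 ± 0.068) and ARR15 (0.77 ± 0.12), whereas 6 fell in the double mutant against atg2-4 (adjusted p = 5.89e-07; 0.0116). Their interaction was negative for 8 of 9 genes (adjusted p = 2.73e-11; 0.00559), with ARR7 at −1.68 ± 0.096. Camalexin and cyanogenic defence genes were higher in atg2-4 in 7 and lower in 2 of 9 cases (adjusted p = 3.76e-04; 0.135 with an estimated correlation), with CYP71A12 at 4.67 ± 0.073 and FOX1 at 2.57 ± 0.083. They were also higher in lon2-8 (6 of 9, adjusted p = 1.68e-05; 0.0968 with an estimated correlation), in the double mutant against Col-0 (7 higher and 2 lower, adjusted p = 8.25e-05; 0.110) and against atg2-4 (5 higher, adjusted p = 7.38e-05; 0.110). Late embryo and dehydration genes rose in 6 and fell in 1 of 10 cases in the double mutant against atg2-4 (adjusted p = 1.29e-05; 0.0507), TIP3;1 (1.11 ± 0.14) and LEA18 (1.07 ± 0.11) among them.

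The 5 comparisons of 3 against 3 libraries allow 10 splits each, too few for a share under 0.05. The real split, 1 of 10 in each, gave 10027 genes for atg2-4, 4779 for lon2-8 and 10753 for the double mutant against Col-0. It gave 1835 for the double mutant against atg2-4 and 10305 against lon2-8. The highest of the other splits gave 0 in each. Those splits mix libraries of the genotypes compared, which widens the spread within groups, so their 0 does not show what chance gives.

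The remaining LON2 transcript was 44.8% of the Col-0 level in lon2-8 and 21.4% of the atg2-4 level in the double mutant, and that of MAD1 39.4% and 20.8%. Of the 39 tested genes among the 25 neighbours of LON2 on either side, 4 changed by over 0.5 log2 in lon2-8. This is a larger share than the 4.68% of all tested genes. Whether so few genes differ from that share by more than chance was not tested.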
